A study of Mus musculus with 12 samples.

How the data were processed

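RNA of gastrocnemius, a mixed but mostly fast-twitch calf muscle, was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, which measure whole transcripts with probesets of short probes. There were 12 arrays in 4 groups of 3: sedentary wild type, sedentary ERRα-null, wild type 2 h after running to exhaustion, and ERRα-null 2 h after running to exhaustion. Per the labels, the mice were FVB males and the 3 arrays of a group are biological replicates. The deposited values are log2 expression values, 1 column per array, and per the submitters' processing notes the authors used RMA, Affymetrix Expression Console and Transcriptome Analysis Console. RMA corrects background, forces the arrays onto a common distribution and summarises probes into a probeset value. Versions, options and the genome build are not given in the sources used here. A common distribution removes any change shared by most genes, so every difference below is relative to the bulk of the transcripts. Summaries over many probes also compress changes of dim transcripts.

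Groups were taken from the sample titles, whose genotype and state follow the stated design. Another label, the source name, gives a different exercise state for the arrays of 2 of the groups, sedentary ERRα-null and exercised wild type. Esrra and heat shock values per array are given with the results for that reason. The values of the 12 arrays were compared before use. Median log2 values ran from 5.15 to 5.26, Pearson correlations across genes between pairs of arrays ran from 0.953 to 0.990, and no pair was identical. Arrays have no read depth, and the number of arrays limits the precision.

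The platform table pairs 23521 of the 41345 probesets with 1 gene symbol, 1814 with several and 16010 with none. Only probesets with 1 symbol were named, and 23328 of these matched the RefSeq gene table of assembly GRCm38.p6, which was used for symbols and gene order only. For the 1082 genes with several probesets, the probeset with the highest mean over all arrays stood for the gene. That left 22180 genes. The 40% with the lowest mean, under a log2 value of 5.32, were not tested, so that 13308 genes were tested in each of 7 comparisons. Among the called genes that have several probesets, the probesets disagreed in sign for 1 of 7 for genotype after exercise, 7 of 38 for exercise in wild type, 1 of 11 for exercise in ERRα-null muscle, and 16 of 65 for exercise averaged over genotypes.

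Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with the 4 group means was fitted to all 12 arrays with 8 residual degrees of freedom, followed by eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method. All tests were two-sided. A gene was called changed at an adjusted p under 0.05. The comparisons were genotype in sedentary mice, genotype after exercise, exercise in each genotype, the interaction of both factors, and the average effect of each factor. Values after ± are standard errors of the model unless SD is written. The adjusted p-values given for single genes are those of limma.

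Before the data were examined, 41 gene lists of muscle metabolism, stress, contractile and cell type transcripts were fixed, with 886 entries of which 811 were on the array. The 39 lists with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the lists. The neutrophil and erythroid marker lists had too few tested members. Each test was repeated with the correlation estimated from these arrays, and with fry, which asks whether the genes of a list move one way on balance. A list is said to have passed when the test at the preset correlation passed, and the adjusted p with an estimated correlation stands beside it. For the averaged comparisons, the mean of a list per array was also compared in an exact permutation test within strata, with 400 arrangements and a smallest possible p of 0.005. For the interaction, residuals of the model without it were rearranged in all 924 ways, with a smallest possible p of 0.00216. Both permutation tests were added after the data were seen.

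The genes named in the text follow a rule fixed before the data were examined. They are Esrra, up to 10 called genes with the largest change in each direction and no overlap between arrays (none required for averages and the interaction), up to 4 members of a list with the smallest p, and 22 further regulators of muscle metabolism that were tested. Where fewer than 5 genes were called in a direction, those with the smallest p fill up to 5. Predicted loci were left out. Cpt1b of this set has no probeset of its own and was not analysed here. Coordinates are not given, because the build of the deposited values is not named.

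The model was tested on simulated arrays with 200 changed genes among 13308. For genotype in sedentary mice it recovered 53.7% of changes of 0.5 log2 and 94.0% of changes of 1 log2. For the interaction it recovered 11.9% and 70.1% of such changes, and for genotype averaged over both states 79.1% and 95.5%. The simulated genes varied independently, with the spread of each real gene. No simulated array differed from its group in sex or other-tissue RNA, so these rates may not hold for the real arrays. Replicate numbers are shared by the groups, so it was checked whether equal numbers pair the arrays. The deviations of arrays with equal numbers from their group means correlated at 0.312, 0.207 and 0.174 between exercised wild-type and exercised ERRα-null muscle, all above 0.1. The labels state no pairing, and this pair of groups was picked by its values. Deviations of 3 arrays sum to 0, which ties these correlations together. In both groups Xist, a transcript of females, was low in replicate 1 and high in replicate 3. A pairing cannot be told apart from that difference. For that comparison the fit with the number as a block is printed beside the result. Alternatives to the filter, the normalization, the probeset rule, the variance model and the threshold, and leaving out each array, were also run, as were fits without doubtful arrays.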

Results

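ERRα, the estrogen-related receptor alpha encoded by Esrra, is an orphan nuclear receptor that activates genes of mitochondrial energy metabolism. The series asks which transcripts of gastrocnemius muscle depend on it at rest and after acute exercise. Transcript levels were measured in wild-type and ERRα-null mice aged 2 to 3 months, either sedentary or 2 h after running to exhaustion on a treadmill, with 3 arrays in each of the 4 groups.

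Esrra was measured first. Its log2 level was 7.53 ± 0.11 (SD, n = 3) in sedentary wild-type muscle and 6.71 ± 0.17 (SD, n = 3) in sedentary ERRα-null muscle, and 7.50 ± 0.12 and 6.72 ± 0.14 (SD, n = 3 each) after exercise. Wild-type arrays ran from 7.41 to 7.63 and ERRα-null arrays from 6.55 to 6.89, so that the genotypes did not overlap on any array. The fall of Esrra was −0.82 ± 0.11 log2 at rest (adjusted p = 0.0238) and −0.78 ± 0.11 after exercise (adjusted p = 0.0227). At rest it did not pass with the replicate number as a block (adjusted p = 0.0590), with only the arrays compared (adjusted p = 0.177) or without the 3 arrays of female profile described below (adjusted p = 0.101), at the same value. After exercise it did not pass with only the arrays compared (adjusted p = 0.0638) or without those 3 arrays (−0.70, adjusted p = 0.397). The signal did not drop to background, and some probes may lie outside the deleted part of the gene, in which case they do not report on the deletion. The mean of the heat shock chaperones, which rise with exercise, lay between −0.49 and −0.28 (log2, centred) on the 6 sedentary arrays and between 0.15 and 0.65 on the 6 exercised arrays, as the sample titles sort them.

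Transcripts of the sex chromosomes and of other tissues, chosen after their values were seen, differed between arrays of a group. Xist, expressed from the inactive X chromosome of females, was at 7.82 to 7.90 on 3 arrays (exercised wild type replicate 3, exercised ERRα-null replicates 2 and 3) and at 3.66 to 4.30 on the other 9. The Y-linked Eif2s3y was at 4.97 to 5.20 on those 3 arrays and at 7.83 to 8.45 on the others, although all samples are labelled male. Alb, the serum albumin of liver, ran from 6.24 in sedentary ERRα-null replicate 3 to 12.82 in sedentary wild type replicate 1. Ucp1 of brown fat was at 10.82 and 10.93 in sedentary wild type replicates 2 and 3, at 9.43 in sedentary ERRα-null replicate 3, and at most 6.24 on every exercised array. The B-cell transcript Cd79a was at 7.97, 7.78 and 8.95 in sedentary wild type replicates 2 and 3 and sedentary ERRα-null replicate 1, and at most 5.47 on the other arrays. Svs5 of the seminal vesicle was at 12.98 in sedentary ERRα-null replicate 1 and at most 4.49 elsewhere.

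**Figure D1:**
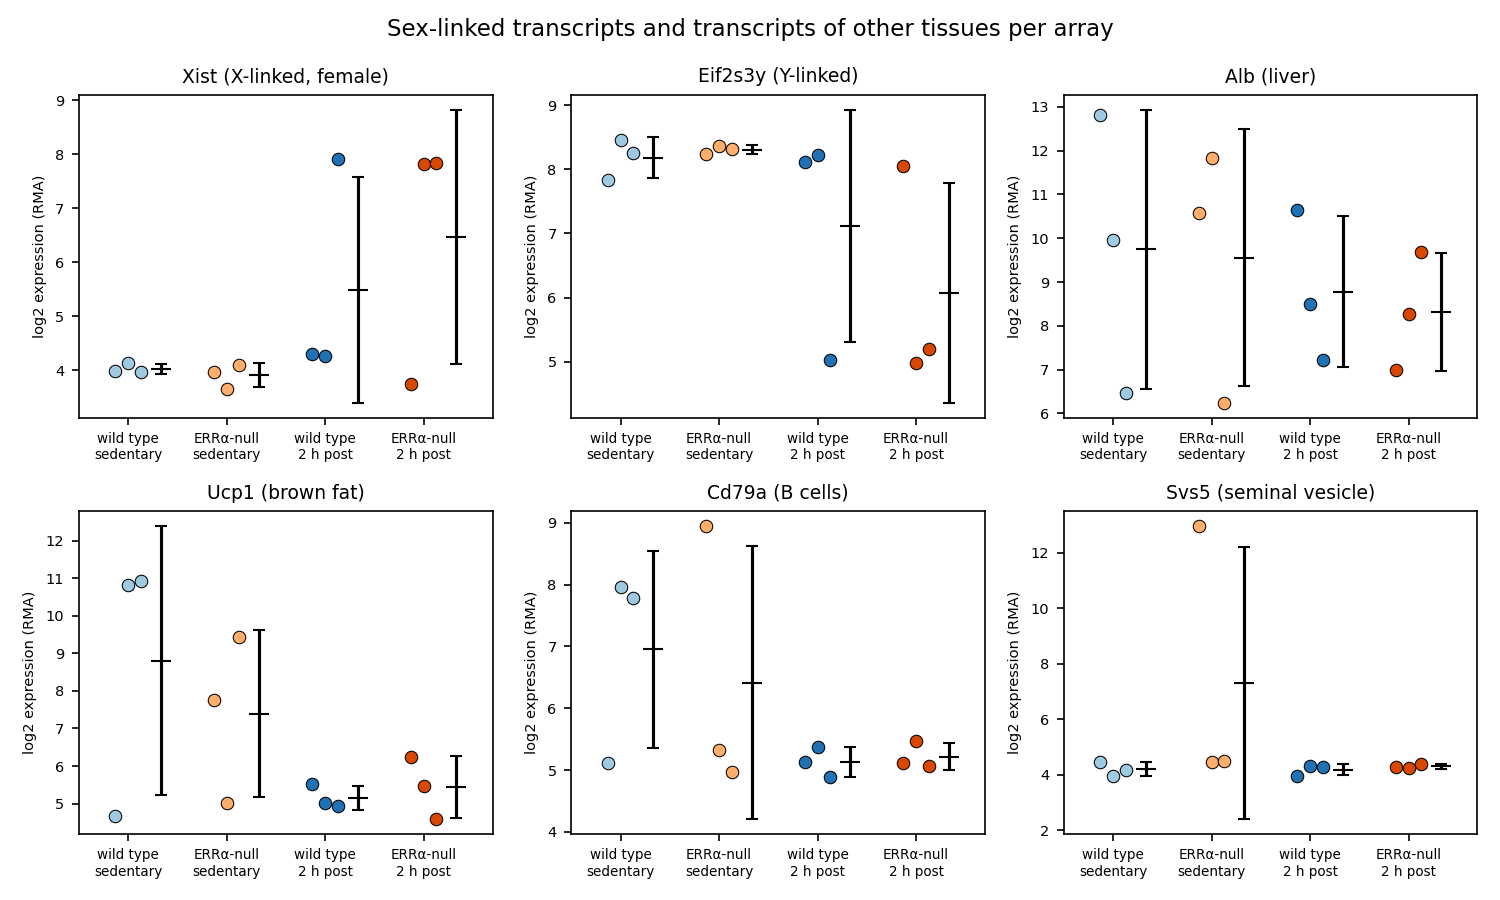
Log2 expression of Xist, Eif2s3y, Alb, Ucp1, Cd79a and Svs5 on each of the 12 arrays, by group, with points for arrays and bars for the mean ± SD of 3 arrays. Xist lies above 7.8 and Eif2s3y below 5.3 on 3 exercised arrays, and Ucp1 and Cd79a reach their highest values on sedentary arrays.

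In resting muscle, the lists of respiratory chain subunits lay lower in ERRα-null than in wild-type mice, with an adjusted p of 0.156 for complexes I, IV and V and 0.225 for complexes II and III with an estimated correlation, and Nr4a3 and Pdk4 were higher. Each of the 32 measured subunits of complex I lay below wild type, with a mean of −0.29 log2, as did the 13 of complexes II and III (mean −0.29) and the 16 of complex V (mean −0.26). Nr4a3, an orphan nuclear receptor induced by muscle contraction, was 3.33-fold higher (log2 1.74 ± 0.22, adjusted p = 0.0159, from a dim wild-type level of 5.36). Pdk4, the kinase that inhibits pyruvate dehydrogenase and so spares glucose, was 1.76-fold higher (log2 0.81 ± 0.10, adjusted p = 0.0159).

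In all, 11 of 13308 genes passed for genotype at rest, 7 higher and 4 lower. Besides Nr4a3 and Pdk4, the higher genes were Cabcoco1 (13.5-fold, log2 3.75 ± 0.18), Arrdc3 (1.0), Cetn2 (0.86), Ctsf (0.72) and Ctnna3 (0.50). Arrdc3 is an arrestin-domain protein, Cetn2 a centrin and Ctsf a lysosomal protease. The lower genes were Frzb, a secreted Wnt antagonist (−1.53), Esrra, Mrpl34 of the mitochondrial ribosome (−0.54) and Ndufb9 of complex I (−0.39 ± 0.06, adjusted p = 0.0391). With the replicate number as a block Cabcoco1, Nr4a3 and Pdk4 kept the call and the other 8 did not, at the same values (adjusted p from 0.0590 to 0.0792). Arrdc3 did not pass with liver, adipocyte and lymphocyte scores as covariates (0.99, adjusted p = 0.0670). Ndufa4 (−0.49, adjusted p = 0.0515), Mfn1 (−0.55), Ndufa8 (−0.54) and Sdha (−0.38) did not pass. At an unadjusted p under 0.05 there were 1094 genes where chance gives 665, and the arrays of the genotypes did not overlap for 13.4% of genes where chance gives 10%.

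Of the 39 lists, 20 passed for genotype at rest, 11 lower and 9 higher, and none held with an estimated correlation. Adjusted over the list alone, 24 subunits of complex I fell, as did 6 of complexes II and III, 6 of complex V and 5 of the 16 of complex IV (list mean −0.22). The 18 tricarboxylic acid cycle genes lay at −0.21 and fell for 10 members adjusted over the list alone (with an estimated correlation, adjusted p = 0.271). Genes of fatty acid oxidation lay at −0.12, with 10 members lower and 1 higher adjusted over the list alone (with an estimated correlation, adjusted p = 0.346). Mitochondrial dynamics (−0.12) and mitochondrial translation (−0.12) passed too, with adjusted p = 0.352 and 0.445 with an estimated correlation. Lipid synthesis (−0.28), endothelial markers (−0.20) and extracellular matrix (−0.14) passed with no member called, at an adjusted p of 0.484 each with an estimated correlation. Sedentary wild type replicate 3 had the highest Ucp1 value, and without it the lipid synthesis mean was −0.0209 and the list test turned to the other direction (adjusted p = 0.987). It was −0.53 without sedentary wild type replicate 1 and −0.11 without sedentary ERRα-null replicate 2 (adjusted p = 0.405). Extracellular matrix ran from −0.28 without sedentary ERRα-null replicate 2 to −0.06 without replicate 1 and lost the call without replicate 1 of either group, wild type replicate 2 or ERRα-null replicate 3 (adjusted p from 0.0684 to 0.153). Endothelial markers lost it without ERRα-null replicate 3 (−0.17, adjusted p = 0.0501). Without sedentary ERRα-null replicate 1 the tricarboxylic acid cycle lay at −0.13, fatty acid oxidation at −0.07, mitochondrial dynamics at −0.06 and mitochondrial translation at −0.04, and each still passed.

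Among the lists that were higher at rest, the exercise-responsive metabolic genes led, with a mean of 0.42 over 22 members. Of these, 2 passed over all genes (Nr4a3 and Pdk4) and 6 adjusted over the list alone, and the adjusted p with an estimated correlation was 0.0524. Slow oxidative fibre genes were higher by 0.38, where Myh7 and Myoz2, the slow myosin heavy chain and a slow-fibre Z-disc protein, had values of 0.77 and 0.51 and did not pass (with an estimated correlation, adjusted p = 0.346). Glucocorticoid targets (0.38) and immediate early genes (0.31) passed as lists with no member called over all genes, and their adjusted p with an estimated correlation was 0.156 and 0.271. Interferon response (0.20), atrophy (0.18), myogenesis (0.12), unfolded protein response (0.10) and ribosomal protein genes (0.09) passed at the preset correlation, with adjusted p between 0.338 and 0.458 with an estimated correlation. Without sedentary ERRα-null replicate 1, where Cd79a was highest, interferon response lay at 0.09 (adjusted p = 0.354) and the unfolded protein response at 0.03 (adjusted p = 0.850), and the latter lost its call also without sedentary wild type replicate 2 (adjusted p = 0.0578) or 3. Atrophy genes lost theirs without wild type replicates 1 or 2 or ERRα-null replicate 3 (adjusted p from 0.0775 to 0.0923), and myogenesis genes, at 0.06 to 0.07, without wild type replicate 3 or ERRα-null replicates 2 or 3 (adjusted p from 0.127 to 0.299). Myogenesis lay at 0.22 without ERRα-null replicate 1 and immediate early genes at 0.21 without replicate 2, and both passed. The count of 11 genes was 2, 1 and 9 without sedentary wild type replicates 1, 2 and 3, and 4, 2 and 4 without sedentary ERRα-null replicates 1, 2 and 3. Without the 3 arrays of female profile, none of them sedentary, it was 4.

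After exercise, the lists of the respiratory chain, the tricarboxylic acid cycle, chaperones and antioxidant genes lay lower in ERRα-null muscle, with adjusted p between 0.0670 and 0.0993 with an estimated correlation. Complex I subunits lay at a mean of −0.32 log2, complexes II and III at −0.36, complex V at −0.30, complex IV at −0.24 and the tricarboxylic acid cycle at −0.30, with every measured member below wild type. Sod2, the mitochondrial superoxide dismutase, fell by 0.56 (± 0.09, adjusted p = 0.0227), and of the chaperones Hsp90aa1 (−0.81) and Hsph1 (−0.72) passed. Over all genes these were 1 of 25 antioxidant genes and 2 of 20 chaperones. Hsp90aa1 did not pass with the replicate number as a block over all arrays (adjusted p = 0.0519) and did on the exercised arrays alone (adjusted p = 0.0171). Hsph1 lost its call in 8 settings, among them the scores of other tissues (−0.73, adjusted p = 0.0622), median centring (adjusted p = 0.0600) and the fit without the arrays of female profile (−1.01, adjusted p = 0.132), and without any exercised array other than ERRα-null replicate 2. Slc16a1, the lactate carrier MCT1, was at 0.554-fold of wild type (log2 −0.85 ± 0.12, adjusted p = 0.0227).

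Genotype after exercise had 50 called genes, 12 higher and 38 lower. Cabcoco1 was highest (15.9-fold, log2 3.99 ± 0.18), then Tceal7 (1.53), Sytl2 (1.04), Gamt (0.99), Hs6st2 (0.95), Mettl11b (0.81), Fbxl22 (0.66), As3mt (0.62), Rps6kc1 (0.54) and Trmt112 (0.50). Gamt makes creatine, and Sytl2 acts in vesicle transport. The largest falls were those of Ighm, the immunoglobulin heavy chain of B cells (−2.58 ± 0.38), Impact (−1.61), Slc18a1 (−1.15), Pdxk (−1.12), Ell2 (−1.02), Ciapin1 (−0.91), Mafk (−0.90) and Slc16a1. With the mean of a gene's probesets Ighm lay at −0.39 (adjusted p = 0.930), Ell2 at −0.56 (adjusted p = 0.145) and Ciapin1 at −0.54 (adjusted p = 0.0580), and Ighm lay at −1.77 without the arrays of female profile (adjusted p = 0.132). With the replicate number as a block over all 12 arrays Tceal7, Hs6st2, Mettl11b, Fbxl22, Rps6kc1, Slc18a1 and Ell2 did not pass (adjusted p from 0.0516 to 0.0718). On the 6 exercised arrays alone Hs6st2 and Ell2 passed with the block, and the other 5 did not (adjusted p from 0.0522 to 0.0821). Tceal7 (1.53), Mettl11b (0.82), Fbxl22 (0.60), Rps6kc1 (0.53) and Slc18a1 (−1.14) did not pass with liver, adipocyte and lymphocyte scores as covariates either (adjusted p from 0.0572 to 0.0779). At an unadjusted p under 0.05 there were 1382 genes, and 16.0% of genes had no overlap between the genotypes.

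The mitochondrial genes called after exercise were Ndufa4 (−0.51) and Ndufa1 (−0.54) of complex I, Sdha (−0.43) of complex II, Cycs (−0.53), the electron carrier cytochrome c, Cox4i1 (−0.66) of complex IV, and Pdha1 (−0.53), Dld (−0.43) and Fh1 (−0.46) of pyruvate and tricarboxylic acid metabolism. Acadvl (−0.50) and Acadl (−0.41), acyl-CoA dehydrogenases of fatty acid oxidation, Mfn1 (−0.76), a mitofusin of the outer membrane, and Timm23 (−0.50) of the import machinery fell as well. With the replicate number as a block over all 12 arrays Ndufa4, Acadl and Mfn1 kept the call and the other 9 did not, with adjusted p from 0.0516 to 0.0828. With the block on the 6 exercised arrays alone, where equal numbers correlate, 8 of the 12 kept it, and Ndufa1, Sdha, Dld and Acadl did not (adjusted p from 0.0502 to 0.0611). Acadl did not pass with liver, adipocyte and lymphocyte scores as covariates either (−0.43, adjusted p = 0.0507). Adjusted over the list alone, 26 of 32 subunits fell for complex I, 13 of 13 for complexes II and III, 11 of 16 for complex V, 5 of 16 for complex IV, 14 of 18 for the tricarboxylic acid cycle and 5 of 25 for fatty acid oxidation (list mean −0.23). With an estimated correlation the adjusted p was 0.0971 for complexes I to IV and fatty acid oxidation, 0.0670 for complex V and 0.0993 for the cycle. Mitochondrial dynamics (−0.20, adjusted p = 0.101 with an estimated correlation) and mitochondrial translation (−0.15, adjusted p = 0.333 with an estimated correlation) were lower in 24 of 26 and 49 of 52 members.

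Stress and exercise lists were lower in ERRα-null than in wild-type muscle after exercise. Heat shock chaperones lay at −0.32, with 7 of 20 members lower adjusted over the list alone, exercise-responsive metabolic genes at −0.32 with 7 of 22, and antioxidant genes at −0.24 with 5 of 25 (with an estimated correlation, adjusted p = 0.0670, 0.0565 and 0.0670). Pdk4 (−0.45), Hspa1a (−1.0), Srxn1 (−0.65), Hk2 (−0.59), Vegfa (−0.50) and Ppargc1a (−0.46) did not pass singly. Atrophy (−0.28), immediate early (−0.24), glucocorticoid (−0.22), unfolded protein response (−0.21), macrophage (−0.18) and lactate and pyruvate genes (−0.13) passed as lists, with adjusted p between 0.101 and 0.459 with an estimated correlation. Smooth muscle and pericyte markers (0.21), extracellular matrix (0.13) and ribosomal proteins (0.06) were the higher lists, with adjusted p of 0.333, 0.617 and 0.359 with an estimated correlation. Without the 3 arrays of female profile, which leaves 1 exercised ERRα-null array, they lay at 0.34, 0.10 and 0.02. Without exercised wild type replicate 2 smooth muscle and pericyte markers lay at 0.03 (adjusted p = 0.327), extracellular matrix at 0.03 (adjusted p = 0.458) and glucocorticoid targets at −0.09 (adjusted p = 0.321). Without exercised ERRα-null replicate 2 the call was lost for ribosomal proteins (0.04, adjusted p = 0.0604), macrophage markers (−0.13, adjusted p = 0.136) and lactate and pyruvate genes (−0.10, adjusted p = 0.0953). Without exercised wild type replicate 1 extracellular matrix lay at 0.24 and glucocorticoid targets at −0.33, and without exercised ERRα-null replicate 3 immediate early genes at −0.14 (adjusted p = 0.0459). With the replicate number as a block the 50 called genes became 23 over all arrays and 73 on the exercised arrays alone, where Pdk4, Hspa1a and Vegfa passed as well. Without wild type replicates 1, 2 and 3 they became 3, 10 and 15, and without ERRα-null replicates 1, 2 and 3 they became 17, 15 and 2. Without the 3 arrays of female profile 5 genes were called, where the lone ERRα-null array is assumed to vary like the other groups.

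Averaged over both states, genes of oxidative metabolism fell in ERRα-null muscle. Of the measured genes, 16 of 32 of complex I, 5 of 13 of complexes II and III, 4 of 16 of complex IV, 5 of 16 of complex V and 10 of 18 of the tricarboxylic acid cycle fell, and none rose. Ndufa4 of complex I was at 0.708-fold of wild type (log2 −0.50 ± 0.06, adjusted p = 0.00272), Sdha at 0.757-fold (−0.40), Cycs at 0.720-fold (−0.47), Cox4i1 at 0.657-fold (−0.61) and Atp5g3 of complex V at 0.759-fold (−0.40). Mfn1 fell by 0.66 (± 0.06, adjusted p = 0.00121).

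In this average 190 genes passed, 57 higher and 133 lower. Adjusted over the list alone, 28 subunits of complex I, 13 of complexes II and III, 10 of complex IV, 15 of complex V, 15 genes of the tricarboxylic acid cycle and 14 of the 25 genes of fatty acid oxidation fell. The list means were −0.30 for complex I, −0.32 for complexes II and III, −0.23 for complex IV, −0.28 for complex V, −0.25 for the tricarboxylic acid cycle and −0.18 for fatty acid oxidation. With an estimated correlation the adjusted p was 0.107 for the 4 respiratory lists and 0.124 for the cycle and fatty acid oxidation. The exact permutation test of list means gave an adjusted p of 0.0390 for each of the 4 respiratory lists and 0.0488 for the cycle and for fatty acid oxidation. In both states all 3 ERRα-null arrays lay below all 3 wild-type arrays in each respiratory list. Examples outside the chain were Dld (−0.38), Pdha1 (−0.44), Fh1 (−0.39), Acadvl (−0.47) and Acadl (−0.34). Citrate synthase, Cs, lay at −0.16 and did not pass (adjusted p = 0.109).

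**Figure D2:**
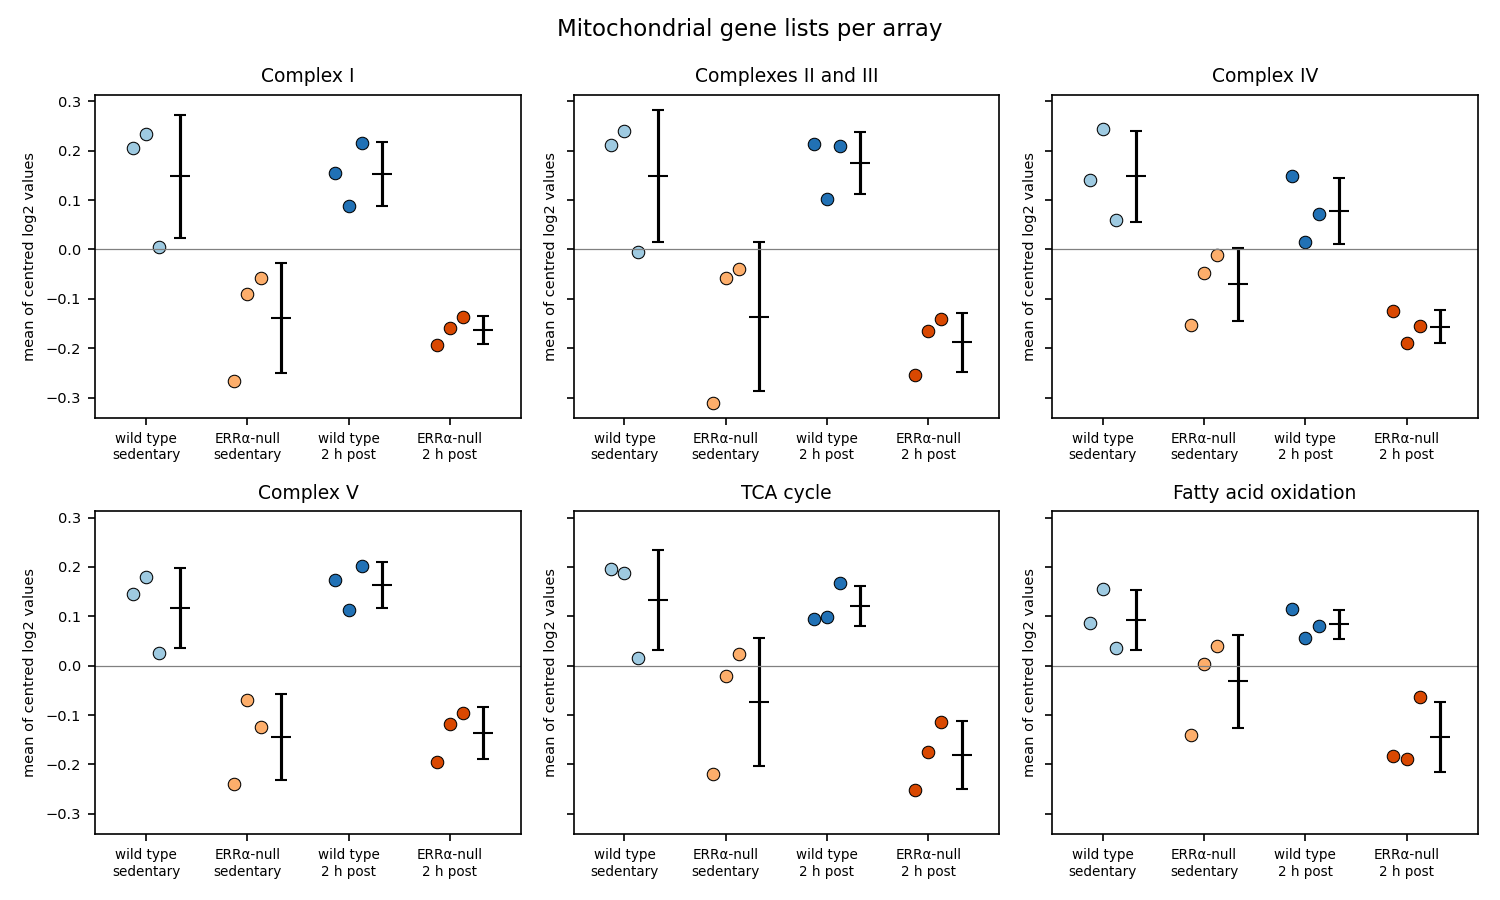
Mean of the log2 values of the genes of 6 lists, centred per gene, for each of the 12 arrays by group, with points for arrays and bars for the mean ± SD of 3 arrays. In the lists of complexes I to V each ERRα-null array lies below each wild-type array of the same state.

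Mitochondrial dynamics and translation were lower in the average as well. Of 26 genes of mitochondrial dynamics and biogenesis 5 fell, among them Mfn1, Timm23 (−0.38) and Immt (−0.33), with a list mean of −0.16 (with an estimated correlation, adjusted p = 0.148, exact permutation test of the list mean, adjusted p = 0.0390). Of 52 genes of mitochondrial translation 4 fell, with Mrpl34 at −0.44 and a list mean of −0.14 (with an estimated correlation, adjusted p = 0.294, exact permutation test, adjusted p = 0.0488). Antioxidant genes lay at −0.14 with Sod2 as the called member (−0.52). The list had an adjusted p of 0.107 with an estimated correlation and 0.0650 in the exact permutation test. The coactivators and relatives of ERRα did not pass: Ppargc1a (−0.01), Ppargc1b (0.32), Esrrb (0.06) and Esrrg (0.07). For Ppargc1a the average joins a higher value at rest and a lower one after exercise, neither of which passed.

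Cabcoco1 was 14.6-fold higher in the average (log2 3.87 ± 0.13, adjusted p = 1.87e-08). Tceal7 (1.25), Gamt (0.89), Sytl2 (0.85), Map3k7cl (0.79), Cetn2 (0.78), Hs6st2 (0.78), Chrnb1 (0.72), a subunit of the acetylcholine receptor, Nr4a3 (0.71) and Atcayos (0.66) followed. Ighm (−1.99 ± 0.27), Frzb (−1.16), Kcng4 (−1.03), Cdc14a (−0.84), Impact (−0.80), Esrra (−0.80 ± 0.08, adjusted p = 0.00121), Flrt1 (−0.80), Cntfr (−0.73), Mfn1 and Slc38a4 (−0.64) fell most. With the mean of a gene's probesets Ighm lay at −0.53 (adjusted p = 0.705), and the averaged call of Nr4a3 joins a rise at rest (1.74) and a value of −0.32 after exercise that did not pass (adjusted p = 0.705). That call was lost in 6 settings, from cyclic loess (adjusted p = 0.0505) to the fit without the arrays of female profile (0.45, adjusted p = 0.246), and without any single array other than exercised ERRα-null replicate 1. Cdc14a (adjusted p = 0.0573) and Slc38a4 (adjusted p = 0.0686) did not pass with the replicate number as a block.

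Slow oxidative fibre genes lay at 0.25 with no member called, Myh7 at 0.53 (list with an estimated correlation, adjusted p = 0.443). With liver, adipocyte and lymphocyte scores as covariates the list lay at 0.16 and passed (adjusted p = 0.00176 at the preset correlation). Smooth muscle and pericyte markers (0.15), myogenesis (0.11, Chrnb1 called) and ribosomal proteins (0.08) were higher, with adjusted p of 0.530, 0.443 and 0.257 with an estimated correlation. Lipid synthesis (−0.15), macrophage markers (−0.15), heat shock chaperones (−0.13), endothelial markers (−0.11), lactate and pyruvate genes (−0.10, with Slc16a1 at −0.57) and angiogenesis genes (−0.08, with Vegfb at −0.24) were lower, with adjusted p between 0.270 and 0.677 with an estimated correlation. Vegfb did not pass with the replicate number as a block (adjusted p = 0.0586). Creatine and calcium handling passed at a mean of 0.01, with Jph1 (0.21) and Ppp3ca (0.25) called (with an estimated correlation, adjusted p = 0.443). Without sedentary wild type replicate 3 the call was lost for lipid synthesis (−0.03, adjusted p = 0.566), macrophage markers (−0.11, adjusted p = 0.0760), myogenesis (0.08, adjusted p = 0.186) and creatine and calcium handling, whose mean changed sign (−0.0013), as it did without sedentary ERRα-null replicate 3 (−0.0089). Without exercised wild type replicate 2 it was lost for smooth muscle and pericyte markers (0.06, adjusted p = 0.402), and without exercised wild type replicate 1 for endothelial markers (−0.05, adjusted p = 0.316) and angiogenesis (−0.04, adjusted p = 0.218). Lactate and pyruvate genes lost it without exercised ERRα-null replicate 2 (−0.08, adjusted p = 0.0758). So did angiogenesis, endothelial markers, lipid synthesis, myogenesis, smooth muscle and pericyte markers, and creatine and calcium handling (adjusted p from 0.07 to 0.0898). Without sedentary wild type replicate 3 angiogenesis, endothelial markers and smooth muscle and pericyte markers lost the call as well (adjusted p from 0.0760 to 0.0876). Other single arrays left out cost several of these lists their call too. Lipid synthesis lay at −0.28 without sedentary wild type replicate 1, smooth muscle and pericyte markers at 0.08 without sedentary ERRα-null replicate 1 (adjusted p = 0.169), and endothelial markers at −0.22 and angiogenesis at −0.14 without exercised wild type replicate 2. Without the arrays of female profile the means were 0.0038 for endothelial markers, −0.08 for lipid synthesis and −0.02 for angiogenesis (adjusted p = 0.804, 0.362 and 0.367). None of the lists in this paragraph passed the exact permutation test (adjusted p from 0.0780 to 0.890). The count of 190 ranged from 79 without sedentary wild type replicate 2 to 251 without sedentary wild type replicate 3, and moved by over 1.5 times without sedentary wild type replicate 1 (89), exercised wild type replicate 1 (126) or exercised ERRα-null replicates 1 (112), 2 (115) or 3 (100). Without the 3 arrays of female profile it was 6, with 1 exercised ERRα-null array left, and 13 lists passed without sedentary wild type replicate 3.

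Exhaustive running changed the transcripts of wild-type muscle within 2 h, with the strongest rises among contraction-induced regulators and heat shock proteins. Nr4a3 rose 36.7-fold, from a log2 level of 5.36 to 10.55 (5.20 ± 0.22, adjusted p = 2.18e-07). The lower level is next to the 5.32 under which genes were not tested, a cutoff by rank and not a detection floor. As changes of dim transcripts are compressed, the fold may be too small. Ppargc1a, the coactivator PGC-1α of mitochondrial biogenesis, rose 5.68-fold (2.51 ± 0.12, adjusted p = 7.08e-07). Hspa1b and Hspa1a, the inducible HSP70 genes, rose 22.0-fold and 16.8-fold (4.46 and 4.07). Of the 22 exercise-responsive metabolic genes 15 rose and of the 20 heat shock chaperones 15 rose, and none of either list fell.

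Of 13308 genes, 457 changed with exercise in wild type, 296 higher and 161 lower. Centring the arrays on their medians moved the share of higher calls from 64.8% to 78.5%. The largest rises after those above were Ankrd1 (3.28), a stretch-responsive muscle ankyrin protein, the stress transcription factor Atf3 (3.01), the metallothionein Mt2 (2.96), Otud1 (2.55), Tnfrsf12a (2.53) and Sik1 (2.36). With liver, adipocyte and lymphocyte scores as covariates Ankrd1 (2.90, adjusted p = 0.0646) and Otud1 (2.04, adjusted p = 0.101) did not pass. Of the further regulators fixed beforehand, Pdk4 rose 2.77-fold (1.47), Ucp3 2.91-fold (1.54), Hk2, which phosphorylates glucose, 2.12-fold (1.09) and Vegfa 1.82-fold (0.86). Esrra did not pass (−0.03), nor did Ppargc1b (−0.52), Ldha (0.06) or Cs (−0.06). At an unadjusted p under 0.05 there were 2145 genes, and 21% of genes had no overlap between the states.

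**Figure D3:**
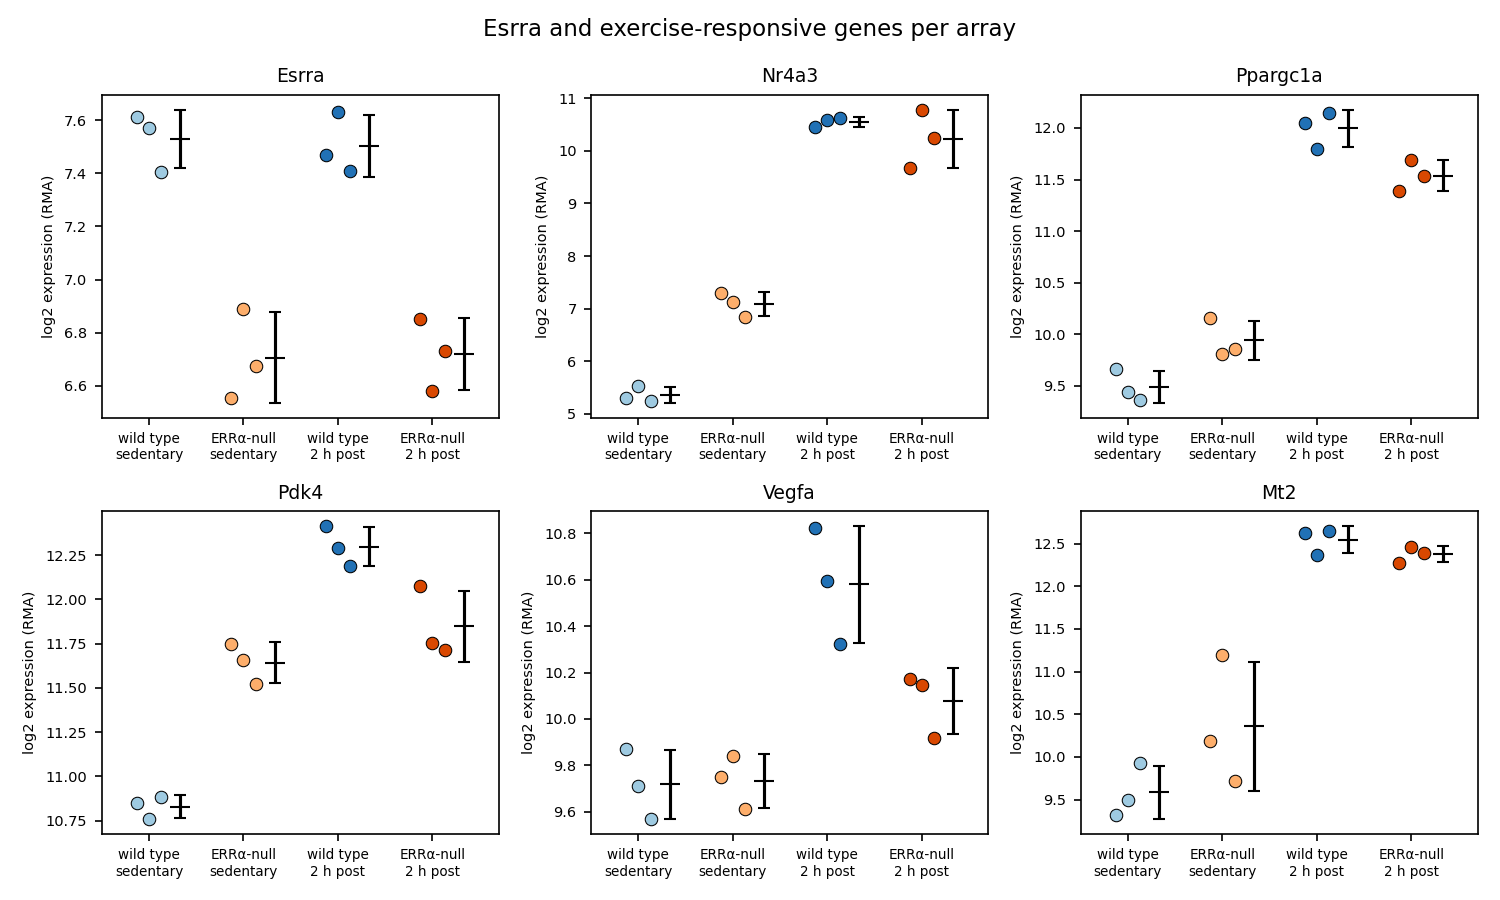
Log2 expression of Esrra, Nr4a3, Ppargc1a, Pdk4, Vegfa and Mt2 on each of the 12 arrays, by group, with points for arrays and bars for the mean ± SD of 3 arrays. Esrra separates the genotypes in both states, and Pdk4 is at 10.83 and 11.64 in the sedentary groups and at 12.30 and 11.85 in the exercised groups of wild type and ERRα-null mice.

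The lists of 13 groups passed for exercise in wild type, 11 higher and 2 lower. Exercise-responsive metabolic genes rose by a mean of 1.44 and heat shock chaperones by 1.01, with Hspb1 (1.42) and Hsp90aa1 (1.46), and both held with an estimated correlation (adjusted p = 0.000684 and 0.00266). Of 25 immediate early genes, 12 rose, with a list mean of 0.84, among them Mafk (1.40), Csrnp1 (1.33), Jun (1.19) and Fos (1.90), and 20 rose adjusted over the list alone (with an estimated correlation, adjusted p = 0.0502). Nr4a2 passed at 1.82 but lay at 1.15 with liver, adipocyte and lymphocyte scores as covariates (adjusted p = 0.262), and Nr4a1 lay at 1.04 and did not pass (adjusted p = 0.181). Of 23 atrophy genes 7 rose, with a list mean of 0.58, Mt1 (2.03) and the muscle ubiquitin ligase Trim63 (1.89) among them (with an estimated correlation, adjusted p = 0.0574). Of 15 glucocorticoid targets 5 rose, such as Zbtb16 (1.44) and Fkbp5 (0.79), with a list mean of 0.63 (with an estimated correlation, adjusted p = 0.102). With the same scores Trim63 (1.67, adjusted p = 0.0646) and Fkbp5 (0.74, adjusted p = 0.0996) did not pass.

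Inflammatory and chemokine genes lay at 0.56, with 4 of 14 called, Lcn2 (1.24), Thbs1 (1.88) and Socs3 (0.99) among them (with an estimated correlation, adjusted p = 0.0925). Myogenesis genes lay at 0.47 with 5 of 22 called, such as Myog (1.12) and Mustn1 (0.73) (with an estimated correlation, adjusted p = 0.118). With the scores of other tissues Myog lay at 1.12 (adjusted p = 0.142) and Mustn1 at 0.80 (adjusted p = 0.0797) and did not pass, nor did the myogenesis list (0.30, adjusted p = 0.0895). The unfolded protein response lay at 0.30 with 6 of 18 called, such as Atf4 (0.65) and Ppp1r15a (0.85) (with an estimated correlation, adjusted p = 0.0925). Of 25 antioxidant genes 4 rose and 1 fell, Srxn1 (2.04), Hmox1 (1.73) and Txnrd1 (0.82) among the risers, with a list mean of 0.26 (with an estimated correlation, adjusted p = 0.293). The regulators of the ERR and PGC-1 axis lay at 0.16 with 4 higher and 1 lower, Lpin1 (0.64) and Ppard (0.72) among the higher, and ribosome biogenesis at 0.13 with Gnl3 (0.60) called, with adjusted p of 0.169 and 0.122 with an estimated correlation. The antioxidant list (0.22, adjusted p = 0.138) and the ERR and PGC-1 list (0.13, adjusted p = 0.0707) lost the call with the scores of other tissues.

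The largest falls in wild type were those of Elovl3, a fatty acid elongase of brown fat (−2.47 ± 0.37), and Thrsp, a regulator of lipid synthesis (−2.32 ± 0.32), then Pck1 (−1.83), Gys2 (−1.61), Cyp4v3 (−1.32), Ces1f (−1.28), Trp53i11 (−1.23), Ano1 (−1.20), Fah (−1.18) and Mc5r (−1.11). The lipid synthesis and storage list lay at −0.64 with Srebf1 (−0.77) called (with an estimated correlation, adjusted p = 0.389), and the lymphocyte markers at −1.05 with none of 7 called (with an estimated correlation, adjusted p = 0.747). Without sedentary wild type replicate 3 the lipid list lay at −0.39 (adjusted p = 0.0373), and the lymphocyte list lost its call without sedentary replicates 2 or 3 (−0.76 each, adjusted p = 0.119 and 0.198) or exercised replicates 1 or 3 (adjusted p = 0.0592 and 0.0906) and lay at −1.63 without sedentary replicate 1. With the score that holds it in the fit, it lay at 0.03. The same arrays differed in other-tissue RNA, with Ucp1 at 10.82 and 10.93 on 2 of the 3 sedentary arrays and at most 5.52 on the exercised ones, and Alb at 12.82 on the third sedentary array. With liver, adipocyte and lymphocyte scores as covariates, Elovl3, Thrsp and Mc5r passed and the other 7 did not, with adjusted p between 0.0831 for Fah and 0.237 for Pck1. Pck1 then lay at −1.0, and the other 6 moved by less than 1.5 times: Gys2 (−1.34), Ano1 (−1.11), Cyp4v3 (−1.06), Trp53i11 (−0.97), Ces1f (−0.96) and Fah (−0.96). None of the scores stands for brown fat alone, so passing with them does not set Elovl3, Thrsp and Mc5r apart from brown fat RNA. With the replicate number as a block Pck1 did not pass (adjusted p = 0.0527). The count of 457 was 233 with those scores, 230 without exercised wild type replicate 3 and the other 2 arrays of female profile, 251 without sedentary wild type replicate 2, 221 without replicate 3 and 243 without exercised wild type replicate 1.

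In ERRα-null muscle, 47 of the 296 genes called higher with exercise in wild type were called higher too. Ankrd1 rose 10.2-fold (log2 3.35 ± 0.45), Nr4a3 8.81-fold (3.14 ± 0.22, adjusted p = 7.55e-05), Hspa1b 7.24-fold (2.86) and Ppargc1a 3.02-fold (1.59 ± 0.12, adjusted p = 0.000128). With liver, adipocyte and lymphocyte scores as covariates Nr4a3 and Ppargc1a passed, and Ankrd1 (3.04, adjusted p = 0.138) and Hspa1b (2.94, adjusted p = 0.0630) did not. Of the 20 heat shock chaperones 7 rose and of the 22 exercise-responsive metabolic genes 5, and none fell. Pdk4 lay at 0.21 (adjusted p = 0.391), and Ucp3 (0.71), Hk2 (0.43), Vegfa (0.34) and Fos (0.77) did not pass either.

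There were 85 called genes, 51 higher and 34 lower, and centring the arrays on their medians moved the share of higher calls from 60% to 76%. Further rises were those of Hspa1a (2.32), Atf3 (2.32), Mt2 (2.02), Tnfrsf12a (1.96), Xirp1 (1.65), Klhl40 (1.63), Mt1 (1.46), Socs3 (1.28), Hspb1 (1.17), Serpinh1 (0.77), Mustn1 (0.68), Lpin1 (0.62) and Bag3 (0.46). Xirp1 and Klhl40 belong to the sarcomere and its maintenance. The largest falls were those of Tfcp2l1 (−1.40), Arrdc2 (−1.24), Rarres1 (−0.97), Arrdc3 (−0.95), Acvr1b (−0.93), Pdp1 (−0.93), Fam214a (−0.86), Trp53inp1 (−0.84), Shld2 (−0.77) and Uckl1os (−0.74). Acvr1b is a receptor for activins, and Pdp1 activates pyruvate dehydrogenase. With the scores of other tissues Hspa1a, Tnfrsf12a and Acvr1b passed and the other genes named here did not, with adjusted p from 0.0702 to 0.209 for the rises and from 0.0862 to 0.185 for the falls. Their values moved by less than 1.5 times, with Mt2 at 2.08, Xirp1 at 1.75, Socs3 at 1.59, Arrdc2 at −1.51, Fam214a at −1.22 and Shld2 at −1.04. With the replicate number as a block Arrdc2, Fam214a, Shld2 and Mustn1 did not pass (adjusted p = 0.0605, 0.0570, 0.0505 and 0.0505). At an unadjusted p under 0.05 there were 1743 genes, and 19% of genes had no overlap between the states.

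Of the lists, 14 passed for exercise in ERRα-null muscle, 9 higher and 5 lower. Exercise-responsive metabolic genes (mean 0.70) and heat shock chaperones (0.62) held with an estimated correlation, at an adjusted p of 0.0141 each. Myogenesis (0.45, 2 of 22 called), inflammation (0.42, 1 of 14), extracellular matrix (0.37, 1 of 24), fibroblast and tendon markers (0.37, none of 14), immediate early genes (0.28, 1 of 25), Schwann cell markers (0.22, none of 8) and the ERR and PGC-1 regulators (0.12, 2 of 20) were the other higher lists, with adjusted p between 0.248 and 0.570 with an estimated correlation. Adipocyte markers (−0.53), lipid synthesis (−0.40), interferon response (−0.33), fatty acid oxidation (−0.11) and the tricarboxylic acid cycle (−0.11) were lower with no member called, and adjusted p between 0.465 and 0.782 with an estimated correlation. Without sedentary ERRα-null replicate 3 the call was lost for adipocyte markers (−0.35, adjusted p = 0.196), Schwann cell markers (0.14, adjusted p = 0.201) and the tricarboxylic acid cycle (−0.06, adjusted p = 0.148). Without replicate 1 it was lost for adipocyte markers (−0.34, adjusted p = 0.329) and the ERR and PGC-1 regulators (0.09, adjusted p = 0.0711), and immediate early genes lay at 0.18 and passed. Without replicate 2 adipocyte markers (−0.90) and Schwann cell markers (0.34) moved the other way, as did the tricarboxylic acid cycle without replicate 1 (−0.18). With the tissue scores the interferon list lay at −0.03 and its test turned to the other direction (adjusted p = 0.901), Schwann cell markers lost the call (0.14, adjusted p = 0.228), and lipid synthesis (−0.21), myogenesis (0.30) and the tricarboxylic acid cycle (−0.24) kept it. Interferon response (−0.12, adjusted p = 0.212), adipocyte markers (−0.34, adjusted p = 0.295) and lipid synthesis (−0.25, adjusted p = 0.0799) did not pass without the arrays of female profile. With array weights immediate early genes lay at 0.13 and lost the call (adjusted p = 0.0508). The ERR and PGC-1 regulators, adipocyte markers and Schwann cell markers lost it with them too (adjusted p from 0.142 to 0.148). Ucp1 was at 7.76 and 9.43 on 2 of the 3 sedentary arrays of this genotype, and Cd79a at 8.95 on 1. The count of 85 was 12 with the tissue scores, 16 without the arrays of female profile, 55 and 36 without sedentary replicates 1 and 3, and 32 and 41 without exercised replicates 2 and 3.

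The response to exercise was set against genotype in a test of the interaction, which asks whether the change in ERRα-null muscle differs from that in wild type. Pdk4 passed: it rose 2.77-fold in wild type and lay at 1.15-fold in ERRα-null muscle, a difference of −1.26 ± 0.14 log2 (adjusted p = 0.0121). No other gene passed, with 681 genes at an unadjusted p under 0.05 where chance gives 665. Over the 22 exercise-responsive metabolic genes as a list, the response was smaller in ERRα-null muscle by a mean of 0.74 log2 (interaction −0.74), in 21 of 22 members, and this held with an estimated correlation (adjusted p = 0.00237).

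Genes near the front of the ranking that did not pass the interaction were Nr4a3 (−2.06, adjusted p = 0.139, with a dim level in sedentary wild type), Hspa1a (−1.75, adjusted p = 0.308), Hivep2 (−0.49), Irf2bp2 (−0.78) and, in the other direction, Scarb1 (0.56), Sfrp4 (0.87), Cygb (0.65), Sdc2 (0.64) and Cd248 (0.98). Ppargc1a lay at −0.91 (adjusted p = 0.329), Sik1 at −1.94, Hspa1b at −1.60 and Ucp3 at −0.83. Of the 39 lists, 15 passed, 13 of them lower, and the exercise-responsive list alone held with an estimated correlation. Glucocorticoid targets (−0.59), immediate early genes (−0.56, with Mafk at −0.92 and Csrnp1 at −0.79), atrophy genes (−0.46, with Trim63 at −1.49), heat shock chaperones (−0.39) and the unfolded protein response (−0.31, with Ppp1r15a at −0.67) had an adjusted p between 0.0749 and 0.0792 with an estimated correlation, and antioxidant genes (−0.19) 0.165. In the permutation test of list means these 6 lists and the exercise-responsive list each had an adjusted p of 0.0241, and no other list was under 0.05. The call of Pdk4 was lost with cyclic loess (adjusted p = 0.0507), without the arrays of female profile (adjusted p = 0.0645), and without sedentary wild type replicate 2, sedentary ERRα-null replicate 2, exercised wild type replicates 1 or 2, or exercised ERRα-null replicate 3, with adjusted p from 0.0517 to 0.0709, over a range of alternatives from 0.00121 to 0.0709.

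**Figure D4:**
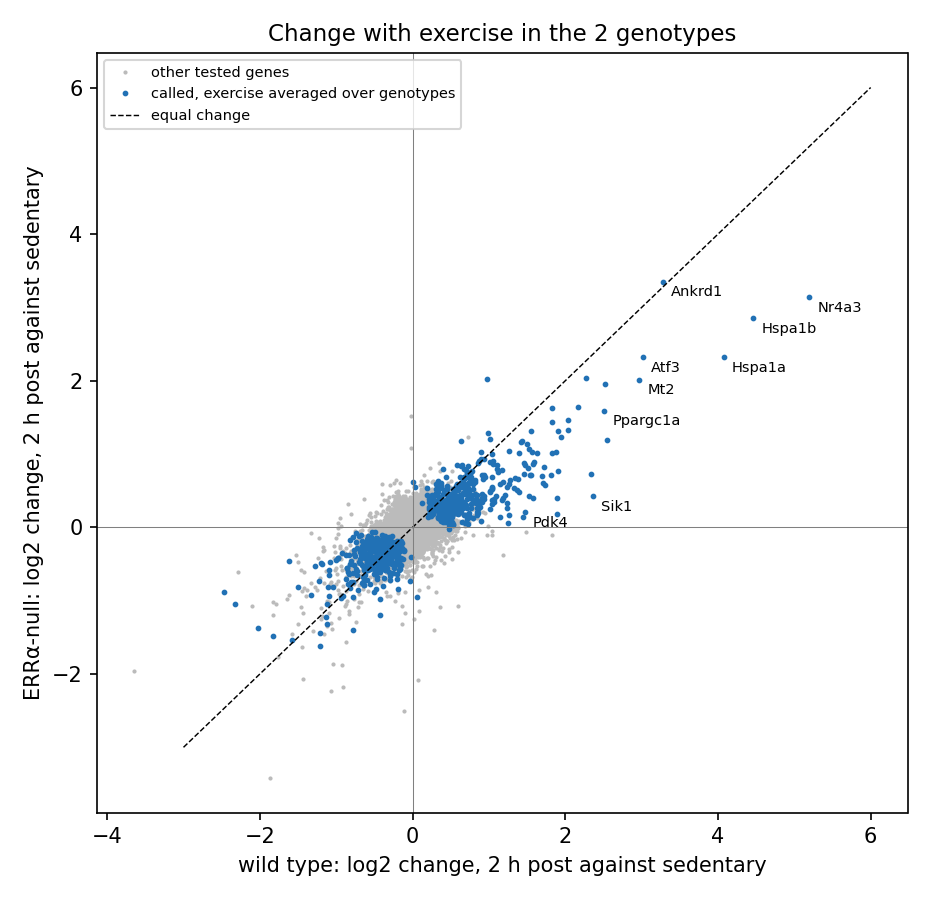
Log2 change with exercise in wild type (horizontal) and in ERRα-null muscle (vertical) for the 13308 tested genes, with genes called for exercise averaged over genotypes in blue and a dashed line of equal change. Of the 418 blue genes that rose, 343 lie below the line, of the 456 that fell, 281 lie above it, and Pdk4 lies at 1.47 and 0.21.

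Called genes of the 2 exercise responses overlapped, and none went in opposite directions. Both responses called 47 higher and 14 lower genes, where independent lists of these sizes would share 1.13 and 0.411. Across all genes, which are not independent replicates, the changes correlated with a Pearson r of 0.666 and a Spearman rho of 0.505, and 439 of the 457 genes called in wild type (96.1%) had the same sign in ERRα-null muscle. The genotype differences at rest and after exercise shared the calls of Cabcoco1 and Esrra, where independent lists would share 0.00631 higher and 0.0114 lower genes, and correlated with an r of 0.272 and a rho of 0.215. Neither pair of comparisons has an array in common, but all come from 1 fit with a shared estimate of the spread of each gene. The counts for independent lists are therefore no exact expectation by chance. In both genotypes Ucp1 and Cd79a were high only on sedentary arrays and Xist only on exercised ones. The 2 exercise responses may share these differences, and with the tissue scores their 61 shared calls became 12.

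Averaged over genotypes, running raised heat shock and contraction-induced genes. Nr4a3 rose 18.0-fold (log2 4.17 ± 0.15), Hspa1b by 3.66, Ankrd1 by 3.31, Hspa1a by 3.20, Atf3 by 2.67, Mt2 by 2.49, Tnfrsf12a by 2.24, Rrad by 2.16, Ppargc1a by 2.05 and Xirp1 by 1.91. Agpat2, which makes phosphatidic acid, fell by 1.70 (± 0.39), and Thrsp (−1.69), Elovl3 (−1.68), Pck1 (−1.65), Cdo1 (−1.56), Slc15a5 (−1.42), Pfkfb3 (−1.33), Dgat2 (−1.22), Ly86 (−1.18) and Slc25a1 (−1.16) followed. Ucp1 of brown fat was at 7.76 or more on 4 of the 6 sedentary arrays and at most 6.24 on the exercised ones. None of the tissue scores stands for brown fat alone. A fall that passes with them is therefore not set apart from brown fat RNA. Without the arrays of female profile Agpat2 (−1.46, adjusted p = 0.317), Slc25a1 (−1.06, adjusted p = 0.344), Thrsp (−1.48, adjusted p = 0.0609) and Elovl3 (−1.70, adjusted p = 0.0782) did not pass. Agpat2 and Slc25a1 did not pass with the sex-linked profile as a covariate (adjusted p = 0.165 and 0.187) or in the robust fit (adjusted p = 0.0723 and 0.0941) either, nor Slc25a1 without a filter on dim genes (adjusted p = 0.0548). With liver, adipocyte and lymphocyte scores as covariates these 4 passed, and the other 6 falls did not: Pck1 (−0.75), Cdo1 (−0.50), Slc15a5 (−0.39), Pfkfb3 (−0.70), Dgat2 (−0.80) and Ly86 (−0.36), with adjusted p from 0.0670 to 0.633. Rrad did not pass with them either (2.68, adjusted p = 0.0504), and without the arrays of female profile Slc15a5 lay at −0.74 (adjusted p = 0.129) and Pfkfb3 at −0.80 (adjusted p = 0.333). In all 874 genes passed, 418 higher and 456 lower, with a share of higher calls of 47.8% that became 65.9% with arrays centred on their medians.

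Of the lists, 18 passed for exercise on average, 13 higher and 5 lower. Exercise-responsive metabolic genes (1.07, 14 of 22 called) and heat shock chaperones (0.81, 16 of 20 called, with Hspb1 at 1.29) held with an estimated correlation (adjusted p = 0.00262 and 0.00349). Immediate early genes (0.56, 14 of 25 higher), inflammation (0.49, 7 of 14, with Socs3 at 1.14), myogenesis (0.46, 7 of 22) and atrophy genes (0.35, 8 of 23 higher and 1 lower) had an adjusted p of 0.111, 0.111, 0.111 and 0.168 with an estimated correlation, and of 0.0433, 0.0279, 0.0279 and 0.0488 in the exact permutation test. Glucocorticoid targets lay at 0.33, with Zbtb16 at 1.31, and extracellular matrix at 0.24, with the collagen chaperone Serpinh1 at 0.77, and had an adjusted p of 0.428 and 0.522 with an estimated correlation. Fibroblast and tendon markers (0.25), creatine and calcium handling (0.16, with the calcineurin regulator Rcan1 at 1.43), the unfolded protein response (0.15), the ERR and PGC-1 regulators (0.14, with Lpin1 at 0.63) and ribosome biogenesis (0.08) had an adjusted p between 0.302 and 0.522 with an estimated correlation. Lymphocyte markers (−0.92), adipocyte markers (−0.52), lipid synthesis (−0.52, with Srebf1 at −0.57 and Dgat2 called), interferon response (−0.20, with Usp18 at −0.40) and fatty acid oxidation (−0.06, with Acadm at −0.23) were lower, with adjusted p between 0.332 and 0.677 with an estimated correlation. With the scores of other tissues Srebf1 (−0.50, adjusted p = 0.0896), Usp18 (−0.34, adjusted p = 0.338), Acadm (−0.35, adjusted p = 0.0896) and Rcan1 (1.0, adjusted p = 0.0528) did not pass. In the exact permutation test the adjusted p was 0.111 for glucocorticoid targets, 0.184 for extracellular matrix, 0.239 for fibroblast and tendon markers, 0.143 for the unfolded protein response, 0.234 for lymphocyte markers, 0.244 for adipocyte markers, 0.185 for interferon response and 0.263 for fatty acid oxidation. It was 0.0279 for creatine and calcium handling, the ERR and PGC-1 regulators and for exercise-responsive and heat shock genes, and 0.0488 for lipid synthesis and ribosome biogenesis. Without sedentary ERRα-null replicate 1 the call was lost for lymphocyte markers (−0.55, adjusted p = 0.0761), adipocyte markers (−0.43, adjusted p = 0.120), interferon response (−0.14, adjusted p = 0.0994) and creatine and calcium handling (0.13, adjusted p = 0.0994), and without exercised wild type replicate 2 for glucocorticoid targets (0.27, adjusted p = 0.0884). Without sedentary wild type replicate 3 adipocyte markers lay at −0.28 (adjusted p = 0.176) and fibroblast and tendon markers at 0.15 (adjusted p = 0.0278). The markers Ucp1 and Cd79a were high only on sedentary arrays, as given above. With the tissue scores the interferon list turned to 0.10 (adjusted p = 0.149) and the lymphocyte list, which the score holds, to 0.01. Glucocorticoid targets (0.19, adjusted p = 0.168), creatine and calcium handling (0.04, adjusted p = 0.780) and ribosome biogenesis (0.05, adjusted p = 0.149) lost the call, and fatty acid oxidation (−0.11), lipid synthesis (−0.34) and myogenesis (0.30) kept it. Interferon response lay at −0.05 without the arrays of female profile (adjusted p = 0.620), and adipocyte markers at −0.79 without sedentary wild type replicate 1. With liver, adipocyte and lymphocyte scores as covariates 153 genes passed in place of 874, 172 passed without the arrays of female profile, and 543 without exercised ERRα-null replicate 2.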

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

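The tests of brown fat RNA after exercise, of the share of muscle fibres, of state labels and of the neighbours of Esrra were chosen after the result was seen, as were the permutation test of the interaction, added because 30 of 100 permutations gave as many lists, and the Ucp1 covariate, added once the other tests of its pattern were known.

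In the test of the interaction Pdk4 (−1.2624 log2) and 15 lists passed at the preset correlation. Of the lists 1 held with an estimated correlation, the other 14 had an adjusted p from 0.0749 to 0.899 with it, and 7 passed the permutation test of list means (adjusted p = 0.0241 each), and 30 of 100 permutations gave as many lists. The list means of the difference were −0.7423 for exercise-responsive metabolic genes, −0.5939 for glucocorticoid targets, −0.5552 for immediate early genes, −0.4573 for atrophy genes, −0.3907 for heat shock chaperones, −0.3059 for the unfolded protein response, −0.2585 for slow oxidative fibre genes, −0.2579 for interferon response, −0.1905 for antioxidant genes, −0.1044 for fatty acid oxidation, −0.0963 for ribosome biogenesis, −0.0954 for the tricarboxylic acid cycle and −0.0785 for mitochondrial dynamics. They were 0.2404 for fibroblast and tendon markers and 0.274 for extracellular matrix. With 1 array left out 6 of the lists lost the call: slow oxidative fibre genes ran from −0.1148 without exercised wild type replicate 3 to −0.3935 without sedentary ERRα-null replicate 1, and fibroblast and tendon markers from 0.0846 without exercised wild type replicate 2 to 0.4384 without sedentary wild type replicate 3. Interferon response lay at −0.1524 without sedentary ERRα-null replicate 1, where the tricarboxylic acid cycle (−0.1689), fatty acid oxidation (−0.1582) and mitochondrial dynamics (−0.1355) kept the call. These 3 lost it without sedentary ERRα-null replicate 3 (−0.0475, −0.0685 and −0.0457), and the cycle lay at −0.0365 without sedentary wild type replicate 3. Extracellular matrix kept its call between 0.165 without exercised wild type replicate 2 and 0.4125 without sedentary ERRα-null replicate 2. The 418 genes that rose with exercise on average rose by a mean of 0.76 in wild type and 0.49 in ERRα-null muscle, with 343 smaller in the latter, 82.1%. The 456 that fell had means of −0.4723 and −0.4039, with 281 smaller in ERRα-null muscle, 61.6%. For the genes that rose, the permutation test of the mean gave p = 0.00216, the smallest it can give. All were picked for their average change over both genotypes.

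For the smaller response of the exercise-responsive list, 3 technical explanations were tested. A wrong state label is argued against by a value. A wrong state label in the sedentary ERRα-null group would put an array among the exercised ones, but the lowest exercised array lay 0.4265 above the highest of that group in the mean of the heat shock list, where the sedentary arrays ranged over 0.2159. Without the arrays of female profile the difference between the responses was −0.8173 in place of −0.7423. Only 1 exercised ERRα-null array is left there, so the value cannot decide about the profile. With liver, adipocyte and lymphocyte scores in the fit the difference was −0.7153 (adjusted p = 2.4e-14 at the preset correlation and 0.05 with an estimated one). Its size argues against RNA of liver, adipocytes and lymphocytes, though the estimated correlation puts the list at the threshold. Brown fat and seminal vesicle had no score of their own, so their RNA was not tested. The list lay at 0.4236 between the genotypes at rest and at −0.3187 after exercise, so that a shorter run before exhaustion might bear on the second part alone, and running times were not analysed here.

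The 4 respiratory chain lists, 77 genes, lay lower in ERRα-null muscle by −0.2666 at rest and −0.3033 after exercise. Brown fat RNA in wild-type samples is argued against by the difference after exercise, where Ucp1 was at most 6.239, and at rest by the value of −0.279 with Ucp1 as a covariate. Without the arrays of female profile the averaged difference was −0.2899 in place of −0.2849. Only 1 exercised ERRα-null array is left there, so the value cannot decide about the profile after exercise. A lower share of muscle fibres would lower the fast and slow fibre lists, which together lay at 0.1405 (exact permutation test, p = 0.075). Most of this came from the slow list (0.254), and the fast list lay at 0.0271. Alb and Svs5 were highest on sedentary wild type replicate 1 and sedentary ERRα-null replicate 1, where the fast list lay at −0.036 and −0.0494. A list that moves so little with RNA of other tissues cannot decide about the share of fibres.

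Among probesets without a single named gene, which no comparison used, 2 of 5648 passed for genotype averaged over states, both higher, and 18 for exercise averaged over genotypes, 16 higher and 2 lower. They were not assigned to genes.

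The splits of the arrays were counted for each comparison, and each count of splits or permutations includes the real one. The 6 arrays of a comparison of groups give 10 splits, too few for a share under 0.05. As many genes as the real split came from 3 splits for genotype at rest (real 11, highest other 113), 1 for genotype after exercise (50 and 10), 1 for exercise in wild type (457 and 0) and 1 for exercise in ERRα-null muscle (85 and 0). As many lists came from 2 splits (20 and 20), 1 (20 and 18), 6 (13 and 18) and 4 (14 and 18). The split with 113 genes set the 3 sedentary arrays with high Cd79a apart from the other 3, which points to a structure of the samples, and the one with 10 genes set apart the 3 arrays of female profile. Of 100 splits within strata, only the real one gave as many genes for genotype averaged over states (190, highest other 42). The same held for exercise averaged over genotypes (874 and 74). A share of 1 in 100 is the smallest these splits can give, so chance is unlikely for these 2 counts but not excluded. Nor do the splits remove differences in sex-linked profile or other-tissue RNA between the arrays. For the lists of both averages 8 (20 and 24) and 12 (18 and 26) of 100 splits gave as many. For the interaction 7 of 100 permutations gave as many genes (1 and 57) and 30 as many lists (15 and 24), so chance is not excluded there.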

How the results depend on the processing

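The fits with sex-linked profile or tissue scores, without the arrays of female profile, with the block on the exercised arrays alone, and both permutation tests of list means were chosen after the data were seen, and the other alternatives were planned. Counts are given in the order genotype at rest, genotype after exercise, exercise in wild type, exercise in ERRα-null muscle, interaction, genotype averaged and exercise averaged (11, 50, 457, 85, 1, 190 and 874 genes), naming those that moved by over 1.5 times. The cause was not tested except where fewer genes or arrays or a stricter threshold give it.

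With the replicate block genotype gave 3 genes at rest and 23 after exercise, and no other of the 7 counts moved by over 1.5 times. With only the arrays compared, genotype gave 4 and 5 and exercise in wild type 232. Without a filter on dim genes there were 23 for genotype after exercise and 54 for exercise in ERRα-null muscle, and with the lowest 60% left out 95 for the former. With every probeset on its own and with quantile normalization again, genotype at rest gave 19 each. Cyclic loess gave 31, 82 and, for the interaction, 0. Without an intensity trend genotype after exercise gave 17, and the robust fit gave 18 and 82 for genotype at rest and after exercise. Array weights gave 53, 161, 268 for exercise in ERRα-null muscle and 363 for genotype averaged. The sex-linked covariate gave 17 for genotype at rest, 303 and 34 for exercise in each genotype, 2 for the interaction and 358 for exercise averaged. Without the arrays of female profile there were 4, 5, 230, 16, 6 for genotype averaged and 172 for exercise averaged. The tissue scores gave 29 for genotype at rest, 233, 12, 300 and 153 for the exercise and averaged comparisons. Adding 1.5-fold left 28, 266, 28 and 227 for genotype after exercise, exercise in wild type and both averages. An adjusted p under 0.1 gave 37, 153, 738, 174, 346 and 1456, and an unadjusted p under 0.05 with 1.5-fold gave 82, 113, 234 for exercise in ERRα-null muscle, 163, 44 and 314.

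With 1 array left out, genes ranged over 1 to 9, 2 to 17, 221 to 354, 32 to 93, 0 to 6, 79 to 251 and 543 to 933, and lists over 17 to 22, 20 to 21, 13 to 17, 11 to 18, 10 to 19, 13 to 21 and 15 to 20. The lists that passed were 0, 0, 2, 2, 1, 0 and 2 with an estimated correlation, and 3, 12, 3 for exercise in ERRα-null muscle, 1 and 8 for genotype averaged with fry. For genotype averaged 13 passed with the lowest 60% left out and 8 in the exact permutation test.

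The 2 genes shared by the genotype differences became 1 with the block, the compared arrays or without the arrays of female profile, 4 with mean probesets, 6 with the sex-linked covariate, 7 with every probeset or tissue scores, 8 with the 60% filter or quantile normalization, 9 with the robust fit, 18 with cyclic loess, 28 with array weights, 23 at an adjusted p under 0.1 and 20 at an unadjusted one, and 1 to 4 with 1 array left out. The 61 shared by the exercise responses became 35 with the compared arrays, 40 without the filter, 143 with array weights, 30 with the sex-linked covariate, 13 without the arrays of female profile, 12 with tissue scores, 126 at an adjusted p under 0.1, 138 at an unadjusted one, and 27 to 58 with 1 array left out. Esrra ranged from −0.8485 to −0.7644 with 1 array left out and did not pass without the arrays of female profile (−0.7615).

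Of 6286 values of 281 gene results, 5330 kept direction and call, 892 lost the call, 64 gained it and none reversed. Of 2960 values of 120 list results, 2521 kept both, 432 lost the call and 7 reversed: lipid synthesis for genotype at rest without WT_pre replicate 3 (−0.0209, the highest of its range with 1 array left out, the lowest being −0.5321), and with tissue scores lymphocyte markers (0.0271 in wild type, 0.0117 averaged), interferon response (−0.0298 in ERRα-null muscle, 0.0983 averaged) and adipocyte markers (0 and 0, by construction, as the score holds the list). A list counts as reversed when its test, which compares with other genes, turned, and in the cases below 0 the mean kept its sign. For genotype averaged the mean alone changed sign for creatine and calcium handling without WT_pre replicate 3 (−0.0013), without KO_pre replicate 3 (−0.0089) and with tissue scores (−0.0156), and for endothelial markers without the arrays of female profile (0.0038).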

Other observations

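In the average over genotypes the clock-linked repressor Nfil3 (1.26) and the matrix protein Thbs1 (1.46) rose, and both passed with liver, adipocyte and lymphocyte scores in the fit (0.96 and 1.40). Of the clock, Arntl (0.74), Per3 (−0.42) and Hlf (−0.38) passed without those scores and not with them, where they lay at 0.59, −0.51 and −0.36, and the circadian list as a whole did not pass (mean −0.10, adjusted p = 0.174). The call was lost with the scores also for the insulin receptor substrates Irs1 (1.11, and 0.55 with the scores) and Irs2 (1.33 and 1.41), the glycogen targeting subunit Ppp1r3c (0.75 and 0.59), the matrix proteins Ccn1 (1.29 and 1.5) and Tnc (0.48 and 0.50) and the syndecan Sdc4 (0.93 and 0.93). Of these genes only Irs1 moved by over 1.5 times. Several of these genes were chosen after their values were seen.

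The test of the neighbours of Esrra was chosen after the result was seen, and the test without the mitochondrial lists was not. The bound for the first test was shortened after its p was seen: as first written, a Fisher p of 0.05 or more would have counted against the explanation, and a p that misses the threshold excludes nothing. Of the 100 tested genes nearest to Esrra in the order of assembly GRCm38.p6, 4 were called for genotype in the average, Trmt112, Vegfb, Trpt1 and Flrt1, against 185 of 13195 others (Fisher's exact test, p = 0.0542). In that order these 4 lay 1, 6, 9 and 14 genes from Esrra, Trmt112 being the nearest (0.47, limma adjusted p = 0.00272). Whether they lie closer than chance gives was not tested. Of all windows of that size, 6.77% held as many. Around Cabcoco1, the gene with the largest genotype difference, 3 of 100 were called, Ctnna3, Mif and Chchd10 (Fisher's exact test, p = 0.17), and 17.3% of windows held as many. Sequence of another strain around the deleted gene and an effect of the deletion itself cannot be told apart from an accident of position, because the called neighbours are few. None of the 4 is a member of the mitochondrial lists, so leaving these lists out could only lower p, and the value without them (0.0193) decides nothing.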
